A study of Mus musculus with 2 samples.

How the data were processed

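The deposited values were made by the authors from Smart-seq3 libraries of sorted single cells. Reads were aligned with STAR 2.7.3a and cells handled with Seurat on the mouse genome GRCm39 (mm39), per the submitters' processing notes; the gene annotation release, the counting program and the strand it counted are not given in the sources used here. The authors deposited raw UMI counts and raw read counts per gene and cell, with introns and exons combined. Per the file headers, a cell table adds the replicate, piece, layer, sex, plate and cell type of each cell, and the authors' quality flag. It also holds the fraction of UMIs from mitochondrial genes, per the file headers, and the intensity of the anti-CD45 stain recorded by the authors at sorting. According to the protocol in the labels, the muscle coat was removed, thermolysin loosened the epithelium from the submucosa, and each layer was cut into 3 equal pieces before digestion and FACS, with part of the cells enriched for CD45. Replicate 1 was digested with trypsin and replicates 2 and 3 with Liberase.

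The tables held 44008 genes and 15949 cells. Of these cells 14162 carried a cell type and were used, 85 of them against the authors' quality flag, and 1787 without a type were left out. Matrix totals per cell ran from 13 to 68039 UMIs with a median of 11403, and from 42 to 1923526 reads with a median of 176233; the matrix totals of UMIs were at the median 1.08 times those in the cell table. The barcode lists and the cell table place replicates 1 and 2 in the first sequencing run and replicate 3 in the second, whereas the sample titles place replicate 1 in one sample and replicates 2 and 3 in the other; the replicate of the cell table was used. Gene names came from GENCODE M21, built on GRCm38, which named 42528 of the identifiers; since the authors' build differs, names only were taken from it and no coordinates are printed. Doublets were not called here, since plates hold 1 sorted cell per well. Genes with close paralogs, such as H2-Q7, Chil4, Hist1h2ap and the keratins Krt6a, Krt14 and Krt16, may share reads with their copies.

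UMI counts were summed over the cells of 1 class, replicate and piece, from the layer to which the class belongs, and sums of 10 or more cells entered. Basal cells comprised the authors' basal and proliferative epithelial types; suprabasal cells, fibroblasts, macrophages, dendritic cells, T cells, mast cells and proliferative immune cells were taken as the authors named them. The numbers of sums were 7 for basal cells (2167 cells), 7 for suprabasal cells (1044 cells), 5 for fibroblasts (2155 cells), 9 for macrophages (4284 cells) and 9 for dendritic cells (640 cells). There were 8 for T cells (215 cells), 5 for mast cells (92 cells) and 6 for proliferative immune cells (193 cells). The sums ranged from 3536369 to 8533167 UMIs in basal cells, from 2619812 to 6347791 in suprabasal cells, from 4484150 to 6471626 in fibroblasts and from 3997063 to 9290363 in macrophages. The smaller classes were shallower, from 103124 UMIs in a T cell sum to 1794705 in a dendritic cell sum. A plate held 1 piece of 1 layer, and most pieces of a layer and replicate filled 2 to 4 plates. Spread between plates of a piece can thus be measured, but an effect shared by all of them cannot be told apart from the piece.

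Each class was fitted in 1 model with piece and replicate as factors, using edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Residual degrees of freedom were 2 for basal and suprabasal cells, 1 for fibroblasts, mast cells and proliferative immune cells, 4 for macrophages and dendritic cells and 3 for T cells. The p-values measure how far differences between pieces vary from batch to batch, and the number of animals pooled in a batch is not given in the sources used here. SE were taken as the absolute fold change over the square root of F. The replicate was kept as a block because the protocol cuts the pieces of a replicate from the same organs. Likeness within replicates was checked, in macrophages and dendritic cells only, by the correlation of deviations from the piece means. Batches also differ in enzyme or sequencing run, so high values show a batch effect but cannot show that pieces share organs. Centring on the piece means also pushes the other pairs towards negative values. Over 7177 genes in macrophages the 9 pairs of the same replicate had correlations of 0.722 to 0.862 and the 18 other pairs -0.749 to 0.122, and over 6862 genes in dendritic cells the pairs of a replicate had 0.498 to 0.664 and the others -0.56 to 0.238. The interaction of basal cells and fibroblasts was tested in 1 fit with class, piece and replicate within class. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and adjusted over the lists tested in a class. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method to the edgeR p-values of a list's own genes.

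The design, the gene lists and the rule for naming genes were fixed before the data were examined. In each class the rule names genes called between the ends, of 2 kinds: those of the fixed lists, up to 15 by smallest adjusted p, and the 8 largest fold changes each way among genes with a mean log2 CPM of at least 4 and the same sign in every replicate with both ends. Predicted genes were passed over, and for the interaction the 5 largest each way were named; 1 gene that the rule names is not reported here. Where one group had 0 UMIs, the fold change is given as a bound over a floor of 3 counts, and with 1 to 3 UMIs as a ratio with an exact 95% counting interval. Shares of cell types were tested by an exact permutation of the pieces within replicates. Values of the stomach piece carry no test. The fits were tested on simulated data made from the sums of each class with planted log2 differences of 1, 2 and 3. The simulation gave a gene the same mean in all replicates and the spread typical of its expression level. Recovery in the real data may therefore be lower. The test recovered 36.1, 80.0 and 83.8% in basal cells, 25.8, 66.7 and 92.6% in suprabasal cells, 21.7, 63.7 and 76.8% in fibroblasts and 51.4, 87.3 and 98.6% in macrophages, so differences near 1 were mostly missed outside macrophages. Genes with no planted difference that were called numbered 0, 3, 1 and 12 in these classes. The authors' types were checked against known genes: 14 of 15 basal progenitor genes were higher in basal than in suprabasal cells, and 20 of 20 squamous differentiation genes lower.

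Alternatives set down beforehand were a fit with no block, DESeq2 1.42.0, median-of-ratios scaling, no filter on low counts, read counts, sums of 30 or more cells, cells thinned to 5000 UMIs, and leaving out each replicate. For lists they were camera with an estimated correlation, fry, no block and read counts, and for shares edgeR on cell numbers and cells of 5000 or more UMIs. Chosen after the data were seen were plates or sexes as units, cells that passed the quality flag, cells of both layers, the stomach piece counted as distal as in the authors' second region column, leaving out the male plates of replicate 2, and the basal class with or without its proliferative type. Scripts used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Expression in endothelial cells, pericytes and the authors' subclusters was not analysed here, and the intensity of the CD45 stain was used as a check only.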

Results

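Single cells of the mouse oesophagus were profiled with Smart-seq3, a plate-based method that counts messenger RNA molecules by unique molecular identifiers (UMIs). The animals were C57Bl/6 mice of 10 to 14 weeks, of both sexes. The tissue was parted into epithelium and submucosa, and each layer was divided into a proximal, a middle and a distal piece, in that order from the mouth towards the stomach. The count tables held 15949 cells, of which 14162 carried a cell type given by the authors. These cells came from 42 plates and 3 experiment batches, called replicates here, and each plate held 1 piece of 1 layer. Replicate 1 gave all 3 pieces of the submucosa but only the distal piece of the epithelium. Replicates 2 and 3 gave all pieces of both layers, and replicate 3 also a piece of the stomach with 1135 annotated cells. Total UMIs per replicate, layer and piece ranged from 5560410 in the stomach submucosa to 17945047 in the proximal submucosa of replicate 2, and the median annotated cell had 12601 UMIs. Gene expression was compared on UMI counts summed per cell class, replicate and piece, so that replicates and not cells were the unit. Fold changes are given as log2 of proximal over distal with their standard error (SE), and expression as CPM on library sizes scaled by TMM, averaged over replicates with both ends.

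The comparison of the end pieces in basal cells asked whether the proliferating layer of the epithelium differs along the organ. Basal cells of the proximal piece expressed far more Tmprss11a, a membrane-anchored serine protease, at 396 CPM against 13.9 in the distal piece (log2 fold change 4.84 ± 0.27 SE, n = 2 replicates with both ends, adjusted p = 2.26e-05). Proximal cells were also higher in Nrg1, a ligand of ErbB receptors (1.85 ± 0.20, adjusted p = 0.00241), in Ptgs2, which encodes cyclooxygenase 2 (2.67 ± 0.33, adjusted p = 0.00596), and in Id1, an inhibitor of basic helix-loop-helix factors (2.64 ± 0.33, adjusted p = 0.00701). Distal cells were higher in Smoc2, a secreted matrix protein, at 275 CPM against 47.9 (-2.54 ± 0.18, adjusted p = 0.000158). Distal expression was also higher for Pappa, a protease that cleaves IGF-binding proteins (-3.94 ± 0.36, adjusted p = 0.00127), and for Tnfrsf19, a receptor of the TNF receptor family (-3.30 ± 0.41, adjusted p = 0.00607). Hoxc8 was not seen among 11787238 proximal UMIs and had 128 among 7729007 distal UMIs of replicates 2 and 3. It was thus at least 65.1-fold higher distally, against a floor of 3 counts over the proximal sums (adjusted p = 0.00470).

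**Figure D1:**
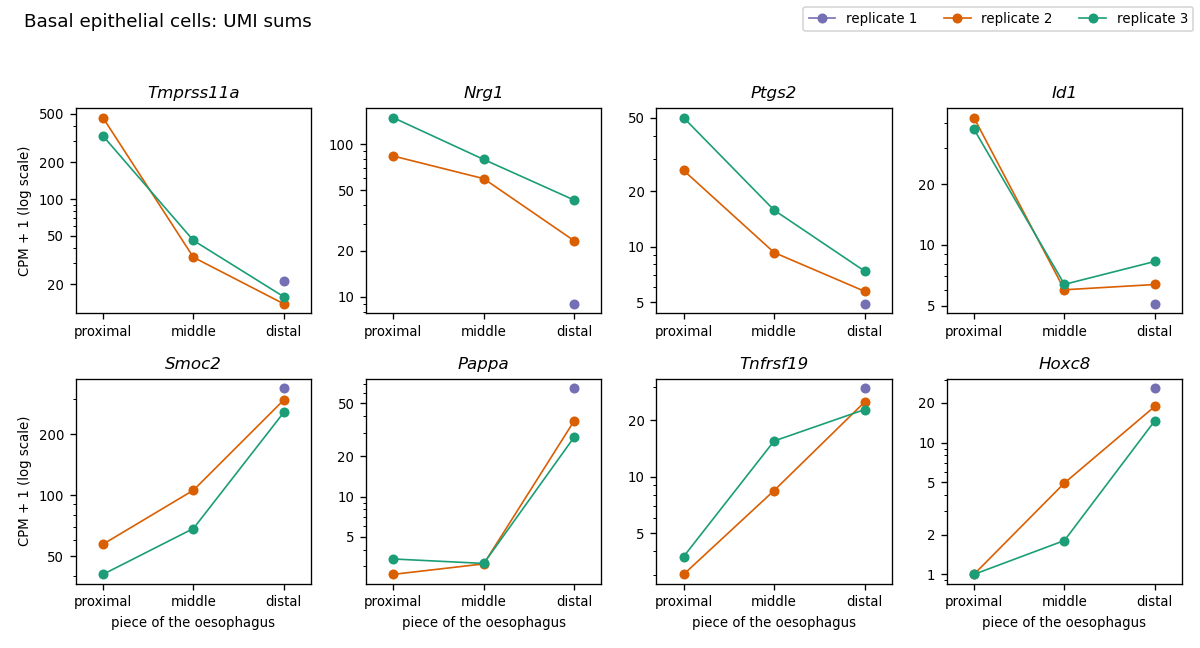
CPM plus 1, on a log axis, of 8 genes in sums of basal epithelial cells, by piece; each point is 1 replicate, and lines join the pieces of a replicate. Replicate 1 has a distal sum only. Tmprss11a averaged 396 CPM in the proximal and 13.9 in the distal piece, and Smoc2 47.9 and 275.

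By edgeR's quasi-likelihood test with the replicate as a block, 105 of 14444 genes differed between the ends of the basal layer, 43 higher proximally and 62 higher distally. The other named proximal genes had log2 fold changes between 0.81 ± 0.13 for the basal keratin Krt14 and 3.13 ± 0.55 for Edn2, a vasoactive peptide. Between them lay Cyp26b1, an enzyme that degrades retinoic acid (2.33 ± 0.33), Upk3bl (1.87 ± 0.28), the secreted lectin Clec11a (1.71 ± 0.29), the homeobox factor Meis2 (1.69 ± 0.23), the activin antagonist Fst (1.62 ± 0.26) and Igfbp2 (1.37 ± 0.20). Krt6a, Krt16 and the zinc-finger factor Klf4 had 1.23 ± 0.20, 1.22 ± 0.20 and 1.06 ± 0.19. The other named distal genes ran from Meis1, a homeobox factor (-1.16 ± 0.19), to the chitinase-like Chil4 (-4.15 ± 0.68). They included Rnf150 (-3.76 ± 0.49), the non-classical MHC class I gene H2-Q7 (-3.68 ± 0.62), Pcdh19 (-3.01 ± 0.43), the immunoproteasome subunit Psmb8 (-2.61 ± 0.41), Hoxc6 (-2.56 ± 0.43) and the leukocyte actin-binding protein Lsp1 (-2.60 ± 0.49; -3.42 in replicate 2 and -1.14 in replicate 3). Their adjusted p-values ran from 0.00820 for Rnf150 to 0.0399 for Lsp1. Without replicate 1, which gave a distal sum only, Hoxc6 had an adjusted p of 0.0533 and 101 genes were called. Without the replicate block the test called 1 gene, and on read counts in place of UMIs it called 0, with 1435 at an unadjusted p under 0.05. DESeq2 on the UMIs called 184. The proximal plate of replicate 2 held females only, and its basal sum had 0.201 CPM of the Y-linked Ddx3y against 13.1 in the distal sum. Without the male plates of that replicate 47 genes were called, and in the proliferative type alone 17.

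Of 263 tested genes in the groups fixed beforehand, 12 were higher proximally and 6 distally in basal cells. Of 22 MHC and interferon-response genes, which serve antigen presentation, none was called higher proximally, 2 were lower (B2m and Psmb8) and 20 were not called, against 14 lower when adjusted over the list alone. Their median log2 fold change was -1.15 (camera adjusted p = 1.28e-17; adjusted p = 0.321 with an estimated correlation). Markers of immune cells moved the same way: 8 pan-immune genes had a median of -2.08, 0 called over all genes and 7 lower when adjusted over the list alone (camera adjusted p = 5.94e-07; adjusted p = 0.321 with an estimated correlation). Medians were -1.77 for 10 macrophage and monocyte genes with 0 called either way (camera adjusted p = 2.58e-08) and -1.14 for 6 dendritic and Langerhans cell genes with Cd207 called, and 2 when adjusted over the list alone (camera adjusted p = 0.000849). The median was -2.17 for 8 T cell genes with 0 called and 4 lower when adjusted over the list alone (camera adjusted p = 0.00905). With an estimated correlation the 3 adjusted p-values were 0.321, 0.321 and 0.411. Lymphatic endothelial genes had a median of -1.39 over 3 genes with 0 called either way (camera adjusted p = 0.0407, or 0.44 with an estimated correlation). Fibroblast markers had a median of -2.01 over 9 genes and extracellular matrix genes -1.43 over 21, neither called by camera (adjusted p = 0.549 and 0.460, direction up). Squamous differentiation genes were higher proximally as a group (20 genes, median 0.37, camera adjusted p = 2.63e-06; adjusted p = 0.321 with an estimated correlation), with Klf4 and Dmkn called, 18 not called, and 7 higher when adjusted over the list alone. Immediate early genes, which tissue dissociation can induce, were higher proximally too (18 genes, median 0.42, camera adjusted p = 1.84e-08; adjusted p = 0.44 with an estimated correlation), with Ier2 called, 17 not called, and 7 higher when adjusted over the list alone.

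Growth factor ligands were higher in proximal basal cells as a group (14 genes, median 0.36, camera adjusted p = 0.000862; adjusted p = 0.321 with an estimated correlation). Nrg1, Igfbp2 and Hbegf were called higher, 11 were not called, and 4 were higher and 1 lower when adjusted over the list alone. Among 15 BMP and TGF-beta genes, Id1 and Fst were higher and 13 were not called, against 4 higher and 1 lower when adjusted over the list alone (median 0.40, camera adjusted p = 0.000803; adjusted p = 0.44 with an estimated correlation). Xenobiotic and redox genes had 0 of 17 called, 6 higher and 1 lower when adjusted over the list alone and a median of 0.32 (camera adjusted p = 0.00312; adjusted p = 0.485 with an estimated correlation). Cell cycle genes had 0 of 25 called, also when adjusted over the list alone, and a median of 0.19 (camera adjusted p = 0.00687; adjusted p = 0.564 with an estimated correlation). Hox genes of paralogue groups 5 to 13 were lower proximally (6 genes, median -1.06, camera adjusted p = 0.0163; adjusted p = 0.417 with an estimated correlation), with Hoxc6 and Hoxc8 called, 4 not called and 3 lower when adjusted over the list alone; the median stayed at -1.06 with Hoxc8 at its bound, and Hoxa5 (0.82) and Hoxa7 (1.31) lay the other way, uncalled. Groups 1 to 4 were higher (6 genes, median 0.74, camera adjusted p = 0.0351; adjusted p = 0.44 with an estimated correlation), with 0 called and 1 higher when adjusted over the list alone. The stress keratin and alarmin group was not called by camera (adjusted p = 0.0929): Krt6a and Krt16 were higher, 6 of 8 genes were not called, and 3 were higher when adjusted over the list alone, with a negative median of -0.22 and mean of -0.068 although the test's direction was up.

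Suprabasal cells, the differentiating layer above, also differed between the ends. Proximal cells were higher in Tmprss11a, at 687 CPM against 42.0 (4.01 ± 0.28, n = 2 replicates with both ends, adjusted p = 0.00230), and in the calcium-binding S100a6, at 1541 CPM against 437 (1.81 ± 0.14, adjusted p = 0.00230). Krt6a, a keratin of activated epithelium, reached 1183 CPM proximally and 247 distally (2.32 ± 0.20, adjusted p = 0.00408), and Krt14 675 and 190 (1.75 ± 0.16, adjusted p = 0.00527). Nrg1 (2.94 ± 0.31, adjusted p = 0.0108), Upk3bl (3.17 ± 0.34, adjusted p = 0.0119) and Id2 (1.98 ± 0.26, adjusted p = 0.0324) were higher proximally as well. Mal had 100 of 6423218 proximal and 2 of 8967603 distal UMIs, a ratio of 69.8 with an exact 95% counting interval of 18.8 to 584 (adjusted p = 0.0324). Distal cells were higher in Dapl1, at 879 CPM against 326 (-1.42 ± 0.15, adjusted p = 0.0108), in the noradrenaline transporter Slc6a2 (-2.06 ± 0.26), in the carboxypeptidase Cpe (-1.69 ± 0.22) and in the tight junction protein Cldn10 (-1.70 ± 0.23, adjusted p = 0.0453). Hoxc8 had 0 of 6423218 proximal UMIs and 82 distal ones, at least 19.6-fold more over a floor of 3 counts (adjusted p = 0.0453).

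In suprabasal cells edgeR's test called 14 of 12451 genes, 8 higher proximally and 6 distally. Without the replicate block it called 0, with 409 at an unadjusted p under 0.05, and on read counts 0, with 781; DESeq2 called 43. Without replicate 1 the adjusted p was 0.108 for Hoxc8 and 0.0534 for Cldn10. Stress keratins and alarmins were higher proximally as a group (10 genes, median 1.67, camera adjusted p = 1.08e-07; adjusted p = 0.523 with an estimated correlation), with Krt6a called, 9 not called and 5 higher when adjusted over the list alone. Immediate early genes were higher too (18 genes, median 0.38, camera adjusted p = 6.09e-05; adjusted p = 0.746 with an estimated correlation), with 0 called either way. So were mitochondrial transcripts (13 genes, median 0.061, camera adjusted p = 0.0229; adjusted p = 0.772 with an estimated correlation), also with 0 called. Basal progenitor genes were also higher proximally in these suprabasal cells (14 genes, median 0.48, camera adjusted p = 2.74e-05; adjusted p = 0.523 with an estimated correlation); Krt14 was called, 13 were not, and 5 were higher and 1 lower when adjusted over the list alone. In basal cells that group was not called (16 genes, adjusted p = 0.181), with Krt14 higher and Tnfrsf19 lower, a median of 0.20 and a mean of -0.054. MHC and interferon genes were lower proximally (20 genes, median -1.01, camera adjusted p = 1.33e-12; adjusted p = 0.523 with an estimated correlation), with 0 called and 11 lower when adjusted over the list alone. Beside them stood 8 pan-immune genes with a median of -1.80, 0 called either way (camera adjusted p = 0.000141; adjusted p = 0.523 with an estimated correlation), and 10 macrophage and monocyte genes with a median of -1.69, also with 0 called (camera adjusted p = 8.98e-06; adjusted p = 0.733 with an estimated correlation). Dendritic and Langerhans cell genes had a median of -1.75 over 5 genes, with 0 called and 2 lower when adjusted over the list alone (camera adjusted p = 0.0238; adjusted p = 0.746 with an estimated correlation). Squamous differentiation genes were not called as a group (23 genes, median 0.07, adjusted p = 0.643). Hox genes of groups 5 to 13 were lower (3 genes, median -3.99, also with Hoxc8 at its bound; camera adjusted p = 6.09e-05; adjusted p = 0.523 with an estimated correlation), with Hoxc8 called, 2 not called and 3 lower when adjusted over the list alone.

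The overlap of the epithelial layers was counted over the 12186 genes tested in both. Krt14, Krt6a, Nrg1, S100a6, Tmprss11a and Upk3bl were called higher proximally in both layers, 6 genes against 0.0282 for independent lists of 43 and 8 genes. Cldn10, Cpe, Hoxc8 and Slc6a2 were called higher distally in both, 4 genes against 0.0261 for lists of 53 and 6. Cells of both layers came from the same plates, so these counts are not independent. Across 6375 genes, which are not replicates, the fold changes of basal and suprabasal cells had a Pearson correlation of 0.535.

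The same comparison was made in fibroblasts, sorted from the submucosa. Proximal fibroblasts expressed Lgr5, a receptor for R-spondins and a target of Wnt signalling, at 107 CPM against 5.09 (4.47 ± 0.25, n = 2 replicates, adjusted p = 0.00207). They were also higher in Thsd4 (2.31 ± 0.18, adjusted p = 0.00804) and in the hedgehog-binding protein Hhip (2.63 ± 0.26, adjusted p = 0.0152). Distal fibroblasts were higher in the matrix protein Cilp, at 509 CPM against 104 (-2.34 ± 0.15, adjusted p = 0.00312). They were higher too in 2 chemokines, the eosinophil attractant Ccl11 (-2.01 ± 0.20, adjusted p = 0.0152) and Cxcl12 (-1.43 ± 0.18, adjusted p = 0.0335). Pld5, Cdh6, Cyp2f2, the complement protease Masp1, Id3 and the Wnt modulator Sfrp4 were higher proximally, with log2 fold changes from 1.14 ± 0.13 for Sfrp4 to 3.54 ± 0.43 for Pld5. Acta2 of smooth muscle actin (-2.18 ± 0.26), the latent TGF-beta binding protein Ltbp1 (-1.73 ± 0.21), the complement regulator Cd55 (-1.32 ± 0.13) and the proteoglycan Aspn (-0.85 ± 0.10) were higher distally.

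**Figure D2:**
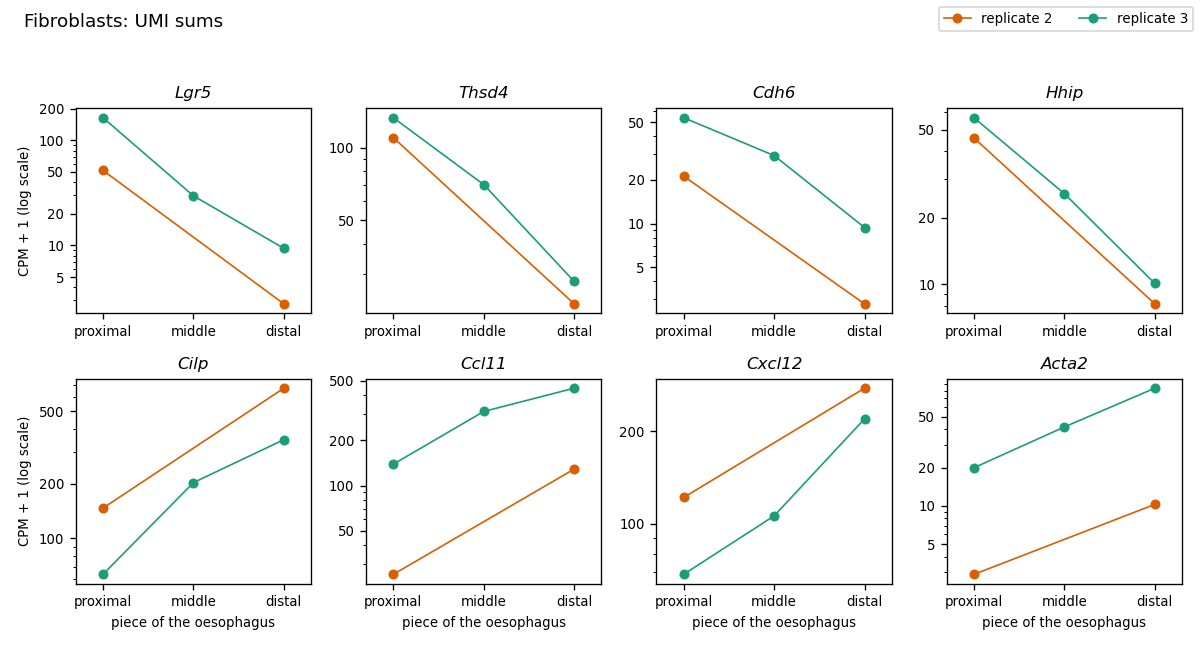
CPM plus 1, on a log axis, of 8 genes in sums of fibroblasts, by piece; each point is 1 replicate, and lines join the pieces of a replicate. Replicate 2 has no middle sum. Lgr5 averaged 107 CPM in the proximal and 5.09 in the distal piece, and Cilp 104 and 509.

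In fibroblasts 29 of 16657 genes were called by edgeR, 21 higher proximally and 8 distally. Without the replicate block 0 were called, with 213 at an unadjusted p under 0.05. The test called 12 on read counts, 135 with cells thinned to 5000 UMIs, 15 with sexes as units and 145 with the stomach piece counted as distal, and DESeq2 called 85. Sexes as units hardly part the sexes here. Of 298 distal fibroblasts of replicate 2, 1 was labelled female and 2 male, of 369 proximal ones 8 and 4, and in replicate 3 0 were. Xist had 84.2 CPM distally and 180.5 proximally in replicate 2, and 307.6 and 271.9 in replicate 3. Of 312 tested genes in the fixed groups, 5 were higher proximally and 2 distally. Wnt response genes were higher proximally as a group (11 genes, median 1.04, camera adjusted p = 5.38e-10; adjusted p = 0.608 with an estimated correlation), with Lgr5 called, 10 not called and 7 higher when adjusted over the list alone. Extracellular matrix genes were lower proximally (29 genes, median -0.14, camera adjusted p = 0.000129; adjusted p = 0.638 with an estimated correlation), with 0 called, and 1 higher and 4 lower when adjusted over the list alone. Hox genes of groups 5 to 13 had a median of -4.29 over 5 genes, or -3.73 with Hoxa7, unseen proximally, at its bound (camera adjusted p = 0.000126; adjusted p = 0.608 with an estimated correlation); none was called and 3 were lower when adjusted over the list alone. BMP and TGF-beta genes were higher (26 genes, median 0.35, camera adjusted p = 0.0179; adjusted p = 0.608 with an estimated correlation), with Id3 called, 25 not called and 2 higher when adjusted over the list alone. Retinoic acid genes had 0 of 13 called, 2 higher when adjusted over the list alone and a median of 0.32 (camera adjusted p = 0.0017; adjusted p = 0.608 with an estimated correlation). Chemokines and cytokines were not called as a group (20 genes, adjusted p = 0.724): Ccl11 and Cxcl12 were lower and 18 not called, against 1 higher and 3 lower when adjusted over the list alone, with a median of 0.13 and mean of 0.032 and a test direction of down.

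Other markers moved with these groups in fibroblasts. Mural and smooth muscle genes were lower proximally (11 genes, median -0.75, camera adjusted p = 0.00505; adjusted p = 0.608 with an estimated correlation), with Acta2 called, 10 not called and 3 lower when adjusted over the list alone. Immediate early genes were higher proximally (18 genes, median 0.32, camera adjusted p = 2.14e-06; adjusted p = 0.608 with an estimated correlation), with 0 called and 4 higher when adjusted over the list alone. Mitochondrial transcripts were higher as well (13 genes, median 0.28, camera adjusted p = 1.56e-07; adjusted p = 0.608 with an estimated correlation), with 0 called and 1 higher when adjusted over the list alone. T cell genes had a median of 1.78 over 13 genes, 0 called and 1 higher when adjusted over the list alone (camera adjusted p = 0.00107; adjusted p = 0.608 with an estimated correlation). Macrophage and monocyte genes had a median of 0.62 over 11 genes (camera adjusted p = 0.00221) and columnar and gastric genes -1.98 over 8 (camera adjusted p = 0.00564). Lymphatic endothelial genes had 0.38 over 6 (camera adjusted p = 0.0381), and mast cell and granulocyte genes -0.80 over 6 (camera adjusted p = 0.0311). All 4 had 0 called either way, and adjusted p-values of 0.608, 0.608, 0.638 and 0.638 with an estimated correlation. The 21 cell cycle genes had a median of 0.80 with 0 called either way (camera adjusted p = 0.00584; adjusted p = 0.608 with an estimated correlation).

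Whether the regional difference itself depended on the cell class was tested as the interaction of basal cells and fibroblasts. Tmprss11a differed most to the basal side among the named genes: its proximal excess was 5.17 ± 0.62 larger on the log2 scale in basal cells (n = 2 replicates, adjusted p = 0.00351), and its fibroblast fold change was -0.09. Pappa differed the other way (-5.17 ± 0.46, adjusted p = 0.000170), with -3.94 in basal cells and 1.25 (adjusted p = 0.162) in fibroblasts. Tnfrsf19 also differed (-4.84 ± 0.49, adjusted p = 0.000514), with -3.30 in basal cells and 1.56 (adjusted p = 0.0783) in fibroblasts, and so did Lgr5 (-4.11 ± 0.72, adjusted p = 0.0333), with 0.21 in basal cells and 4.47 in fibroblasts. Aldh1a2, an enzyme that makes retinoic acid, differed by -4.97 ± 0.62 (adjusted p = 0.00353), with -4.07 (adjusted p = 0.109) in basal cells and 1.08 in fibroblasts. Hoxc4 had nearly equal ends in basal cells (-0.07) and -3.03 (adjusted p = 0.116) in fibroblasts, a difference of 3.11 ± 0.43 (adjusted p = 0.00604). The homeobox gene Pitx1 differed by 2.81 ± 0.44, Ccdc3 by 2.63 ± 0.45, Rpgrip1 by 2.43 ± 0.45 and the histone gene Hist1h2ap by -5.47 ± 1.05, with adjusted p-values from 0.0141 to 0.0477. In basal cells and fibroblasts the log2 fold changes were 0.14 and -2.49 for Pitx1 and 0.55 and -2.04 for Ccdc3. They were 0.99 and -1.43 for Rpgrip1, and -0.28 and 4.71 for Hist1h2ap. EdgeR called none of these genes in either class alone. In all 51 of 18688 genes were called, 14 with the larger log2 of proximal over distal in basal cells and 37 in fibroblasts. A larger value need not be a proximal excess, since for Hoxc4 and Pitx1 it came mostly from a distal lean in fibroblasts. Without the replicate block 0 were called, with 635 at an unadjusted p under 0.05, and on read counts 0, with 1233. In other settings 30 were called with plates as units, 26 without the male plates of replicate 2 and 156 with the stomach piece counted as distal, and DESeq2 called 98. Across 5990 genes, which are not replicates, the fold changes of the classes had a Pearson correlation of 0.0466.

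The middle piece was set against each end to see where along the organ expression changed. In basal cells Tmprss11a (-3.38, adjusted p = 0.000293, n = 2 replicates), Id1 (-2.91, adjusted p = 0.0178) and Id3 (-2.49, adjusted p = 0.0178) were lower in the middle than in the proximal piece, with means of 38.6, 5.18 and 16.7 CPM in the middle. Smoc2 (-1.70, adjusted p = 0.00638), Pappa (-3.88, adjusted p = 0.00499) and Rnf150 (-3.51, adjusted p = 0.0177) were lower in the middle than in the distal piece, while Clec11a (1.79, adjusted p = 0.0435) and Upk3bl (1.68, adjusted p = 0.0467) were higher. By edgeR 3 genes were called between middle and proximal pieces, all lower in the middle, and 28 between middle and distal, 8 higher and 20 lower in the middle. With median-of-ratios scaling the latter were 46, 18 higher and 28 lower. DESeq2 called 22 and 76, and without the replicate block 0 were called in either, with 178 and 305 at an unadjusted p under 0.05. Id3 in the middle piece, and the genes called in the middle of the other classes, were named after their values were seen.

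In suprabasal cells Krt6a (-2.26, adjusted p = 0.0149), Tmprss11a (-2.79, adjusted p = 0.0149) and Klf12 (-2.35, adjusted p = 0.0398) were lower in the middle than in the proximal piece, and Nme5 was higher (3.69, adjusted p = 0.0441), 4 genes in all (n = 2 replicates). Dapl1 was the 1 gene called between middle and distal pieces (-1.75, adjusted p = 0.0125). Median-of-ratios scaling gave 2 genes, 1 of them higher. Without the block 0 were called against either end, with 201 and 188 at an unadjusted p under 0.05 and 16 and 12 by DESeq2. The middle fibroblast sum came from replicate 3 alone and was assumed to vary like the others. It held more keratinocyte transcripts than either end: Krt13 averaged 487 CPM against 47.9 proximally and 55.0 distally, and Krtdap 531 against 28.7 and 34.2. Of 12 genes called between middle and proximal fibroblasts, 7 were higher in the middle, among them Krt13, Krtdap, Krt4, Mt4 and Fabp5 beside Cilp (1.61, adjusted p = 0.0494) and Aspn (1.25, adjusted p = 0.0373), and Lgr5 was lower (-2.57, adjusted p = 0.0438). Krt13, Krtdap, Krt4, Mt4 and Fabp5 were the 5 genes called between middle and distal fibroblasts. Without the block 0 were called in either, with 138 and 173 at an unadjusted p under 0.05, and DESeq2 called 29 and 15.

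Few genes differed between the ends of immune cells in the submucosa, but keratinocyte transcripts did as a group in 3 of the 5 classes. In macrophages Mt4, a metallothionein of squamous epithelium, was the 1 gene called of 14641, at 49.9 CPM proximally and 10.9 distally (2.31 ± 0.22, higher in 3 of 3 replicates, adjusted p = 0.0129). The squamous differentiation genes were higher in proximal macrophages (10 genes, median 1.53, camera adjusted p = 5.88e-09; adjusted p = 0.137 with an estimated correlation), with 0 called and 7 higher when adjusted over the list alone. Krtdap reached 32.9 CPM proximally and 6.86 distally (2.49 ± 0.31, adjusted p = 0.0700), and Krt13 153 and 38.6 (2.11 ± 0.38, adjusted p = 0.149). Dendritic cells had the same group higher (6 genes, median 2.19, camera adjusted p = 4.25e-09; adjusted p = 0.181 with an estimated correlation), with 0 called and 5 higher when adjusted over the list alone, and Krt13 at 113 and 25.3 CPM. Proliferative immune cells did too (5 genes, median 1.95, camera adjusted p = 0.000357; adjusted p = 0.874 with an estimated correlation), with 0 called and 2 higher when adjusted over the list alone. The group was not called in T cells (3 genes, median 0.34, adjusted p = 0.163) or in mast cells (3 genes, median 0.45, adjusted p = 0.503). In the middle piece Krt13 had 145 CPM in macrophages and 126 in dendritic cells, and Mt4 was called between middle and distal macrophages (2.10, adjusted p = 0.0337).

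Other groups moved in immune cells, markers of other cell types among them. Fibroblast markers were higher in proximal macrophages (11 genes, median 0.39, camera adjusted p = 5.17e-05; adjusted p = 0.279 with an estimated correlation) with 0 called and 3 higher when adjusted over the list alone. T cell genes were higher there too (11 genes, median 0.70, camera adjusted p = 0.000169; adjusted p = 0.243 with an estimated correlation) with 0 called and 2 higher when adjusted over the list alone. Mural and smooth muscle genes were lower (8 genes, median -0.63, camera adjusted p = 0.0127; adjusted p = 0.223 with an estimated correlation), and skeletal muscle genes too (4 genes, median -1.38, camera adjusted p = 0.00161; adjusted p = 0.279 with an estimated correlation), with 0 called either way in both. In dendritic cells fibroblast markers were higher with 0 called either way (9 genes, median 0.70, camera adjusted p = 0.000302; adjusted p = 0.263 with an estimated correlation). Cell cycle genes were higher in proximal macrophages (23 genes, median 0.67, camera adjusted p = 7.22e-05; adjusted p = 0.186 with an estimated correlation), with 0 called and 4 higher when adjusted over the list alone. Chemokines and cytokines were higher in proximal macrophages (19 genes, median 0.64, camera adjusted p = 7.30e-05; adjusted p = 0.235 with an estimated correlation) with 0 called and 3 higher when adjusted over the list alone. In dendritic cells the chemokine group was higher too (15 genes, median 0.78, camera adjusted p = 4.81e-06; adjusted p = 0.181 with an estimated correlation) with 0 called and 5 higher when adjusted over the list alone. The rotation test fry, which asks whether the genes of a group move one way on balance, called 5 groups in macrophages, among them squamous differentiation (adjusted p = 0.0324) and cell cycle (adjusted p = 0.0397).

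In T cells Retnla, a secreted protein typical of alternatively activated macrophages, was the 1 gene called of 5211 (1.29 ± 0.18, n = 2 replicates, adjusted p = 0.0159), at 4868 CPM proximally and 2051 distally. Macrophage and monocyte genes were higher in these T cells as a group (10 genes, median 0.51, camera adjusted p = 0.00519; adjusted p = 0.655 with an estimated correlation), with 0 called either way. So were mast cell and granulocyte genes (6 genes, median 1.19, camera adjusted p = 0.00463; adjusted p = 0.355 with an estimated correlation), with 0 called either way. Immediate early genes were higher as well (18 genes, median 0.47, camera adjusted p = 0.000574; adjusted p = 0.355 with an estimated correlation), with 0 called and 3 higher when adjusted over the list alone. In proliferative immune cells the lectin receptor Clec4e was higher proximally (3.01 ± 0.51, n = 2 replicates, adjusted p = 0.0159) and 1 further gene was called of 8373, while DESeq2 called 0. Cell cycle genes were lower proximally there (25 genes, median -0.29, camera adjusted p = 0.000357; adjusted p = 0.874 with an estimated correlation), with 0 called and 3 lower when adjusted over the list alone. Macrophage and monocyte genes were lower with them (10 genes, median -0.57, camera adjusted p = 0.00661; adjusted p = 0.874 with an estimated correlation), with 0 called, and 1 higher and 2 lower when adjusted over the list alone.

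EdgeR called 0 genes in dendritic cells, with 558 at an unadjusted p under 0.05 and 21 by DESeq2, and 0 in mast cells, with 304 and 0. The 4 calls of the 5 immune classes were all higher proximally; with median-of-ratios scaling there were 11, 7 higher and 4 lower. DESeq2 called 77 in the 5 classes, and without the block 0 were called, with 63 to 159 at an unadjusted p under 0.05 per class. The adjusted p of Mt4 was 0.0963, 0.0723 and 0.0517 without replicates 1, 2 and 3, and that of Retnla was 0.0770 without replicate 2. The 4 calls became 28, 0 and 71. Mast cells and proliferative immune cells could be fitted only without replicate 3, so the 28 and 0 cover 3 classes; all of the 28 were in T cells, as were 35 of the 71. The middle piece gave 0 calls in dendritic cells, with 293 and 374 genes at an unadjusted p under 0.05 and 3 and 6 by DESeq2 against the proximal and distal ends, and 0 in T cells, with 162 and 271 and with 1 and 3 by DESeq2. It gave 0 in macrophages against the proximal end, with 710 and 14 by DESeq2. The middle of proliferative immune cells rests on the sum of replicate 1 alone, assumed to vary like the others. There 3 genes were lower in the middle than in the proximal piece, the complement gene C1qa (-2.41, adjusted p = 0.0147), the chemokine Cxcl10 (-2.40, adjusted p = 0.0449) and the mast cell tryptase Tpsb2 (-3.23, adjusted p = 0.0449). Median-of-ratios scaling gave 13 there, 3 higher and 10 lower. Against the distal end 9 genes were called, 3 higher and 6 lower, C1qa (-2.99, adjusted p = 0.00120), C1qb (-1.94, adjusted p = 0.0209) and C1qc (-3.39, adjusted p = 0.00613) among the lower. Without replicates 1, 2 and 3 the calls of the immune classes together were 7, 0 and 39 against the proximal end and 15, 1 and 64 against the distal end, in place of 3 and 10; proliferative immune cells, with 3 and 9 of these, were fitted only without replicate 3.

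Shares of cell types were compared along the pieces within each layer, as the slope in percentage points per piece towards the mouth, with an exact two-sided permutation of pieces within replicates. FACS gates and the filling of plates also set these shares. In the epithelium suprabasal cells had a slope of -6.07 points, proliferative cells 3.69 and basal cells 2.38, each with an exact p of 0.333 (adjusted p = 0.333). Replicates differed: the slopes were -13.1, 7.54 and 5.57 points in replicate 3 and 0.971, -0.162 and -0.809 in replicate 2. Among submucosal immune cells macrophages had -4.18 points (exact p = 0.0648, adjusted p = 0.259), ILC2s 1.41 (exact p = 0.0463, adjusted p = 0.259) and dendritic cells 0.803 (exact p = 0.481). Without replicate 1 the macrophage and ILC2 slopes were -2.41 and 0.799, and that of dendritic cells ranged from 0.505 to 1.34 with a replicate left out. In the stroma fibroblasts had 5.08 points and smooth muscle cells -1.31, each with an exact p of 0.167. These slopes came from replicate 3 for the most part, at 8.62 and -2.58 points against 1.55 and -0.026 in replicate 2. The smallest p these orderings allow is 0.0556 in the epithelium, 0.167 in the stroma and 0.00926 among immune cells, and no type passed after adjustment. EdgeR on the cell numbers called smooth muscle cells, 1 of 6 stromal types (-1.23 on the log2 scale per piece, adjusted p = 0.00948). In replicate 3 they made up 5.86% of 631 stromal cells distally, 2.93% of 920 in the middle and 0.694% of 576 proximally, and replicate 2 had 1 such cell at each end.

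The stomach piece was taken in replicate 3 alone and so has no replicate check; its values stand beside the distal piece of that replicate, with no test. The genes named for it were picked after the data were seen, as those with the largest log2 ratios, with 1 added to each CPM, among genes of at least 64 CPM in one of the pieces. In its basal cells Car2, a carbonic anhydrase, had 600 UMIs (131 CPM) against 0 distally, Gsdmc2 73.8 CPM against 0, and Krt7, a keratin of simple epithelia, 75.3 CPM against 1.39. Krt13, a keratin of the differentiated oesophagus, had 346 CPM against 1688, and Krt32 9.42 against 75.5. Fibroblast transcripts were higher in the basal sum of the stomach piece as well, with Col3a1 at 222 CPM against 8.61. Of the genes that separated the ends, Tmprss11a had 4.60 CPM in stomach basal cells and 13.6 distally, Hoxc8 28.9 and 12.5, and Pappa 70.1 and 24.7. Smoc2 was nearly level, at 254 and 234. The other named proximal genes did not move one way. Some were higher in the stomach sum, as Nrg1 at 74.7 and 38.6, Ptgs2 at 22.6 and 5.83 and Krt14 at 2910 and 1793. Others were lower, as Fst at 5.91 and 15.0, Upk3bl at 7.67 and 41.4 and Igfbp2 at 78.2 and 116. H2-Q7 had 3.72 CPM against 40.0, and Psmb8 4.60 against 39.2. Suprabasal cells of the stomach piece had Krt17 at 1058 CPM against 6.72, Krt1 at 576 against 3.61 and Krt7 at 148 against 1.15, while Dynap had 2.52 against 146. Krt17 had 177 CPM in the proximal suprabasal sum of the same replicate. In its fibroblasts Lgr5 was down to 1 UMI (0.303 CPM) against 8.33 CPM distally, Cilp reached 1044 against 346 and Nrg1 86.6 against 3.83, while Cyp2e1 had 1.21 against 82.6 and Dpp4 6.96 against 98.3.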

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

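The tests of technical explanations below were set down before they were run, except the tests on immune-linked genes and on a common share of epithelial RNA, which were chosen after the results were seen.

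The proximal to distal difference was not the same in basal cells and fibroblasts for 51 genes by a test of the interaction, of which the 5 largest each way are named. The log2 difference of basal cells minus that of fibroblasts was 5.17 for Tmprss11a, 3.11 for Hoxc4, 2.81 for Pitx1, 2.63 for Ccdc3 and 2.43 for Rpgrip1. It was -4.11 for Lgr5, -4.84 for Tnfrsf19, -4.97 for Aldh1a2, -5.17 for Pappa and -5.47 for Hist1h2ap. Tnfrsf19 and Lgr5 both belong to the Wnt response list, and they were called in different classes. Tnfrsf19 was higher in distal basal cells, where Lgr5 had 0.21 (edgeR adjusted p = 0.959). Lgr5 was higher in proximal fibroblasts, where Tnfrsf19 leaned the same way without a call (1.56, edgeR adjusted p = 0.0783). Neither class had the 2 genes called in opposite directions. Aldh1a2 makes retinoic acid and Cyp26b1, higher in proximal basal cells, degrades it. Apart from these genes, a signal stood in data that no comparison uses: 3.0837% of the annotated cells of the stomach piece, 35 of 1135, were named stomach epithelial cells by the authors. The exact 95% interval is 2.16 to 4.26%, for counting error only, and the other pieces had 0 of 13027, with an exact upper limit of 0.0283%. The 1135 cells were 565 of the epithelium and 570 of the submucosa, so FACS gates and plate filling also set this percentage.

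The squamous differentiation list was higher in proximal macrophages, dendritic cells and proliferative immune cells by camera, but with 0 members called and not with an estimated correlation (adjusted p = 0.137, 0.181 and 0.874). RNA carried over from epithelial cells was weighed in fibroblasts of the same layer, where the list had a median log2 difference of 0.2123, with a bootstrap interval over 18 genes of -0.2028 to 0.998, so this test cannot tell. A share common to macrophages and fibroblasts would give fibroblasts the same gain in CPM; over the 10 genes tested in both they fell short of it by a median of -0.6513, with an interval of -1.46 to 0.142, so the test cannot tell, while the 5 genes gaining 10 or more CPM, a limit set after the values were seen, gave -1.70 to -0.969. With cells thinned to 5000 UMIs the list's median in macrophages kept 0.9175 of its size, 1.387 against 1.512 over 9 genes. Thinning keeps the expected share of each gene in a cell, so a ratio near this could be expected either way. The test therefore cannot exclude a difference in depth. Carry-over and a difference in depth stay open, and uptake of keratinocyte material was not tested. An effect shared by all plates of a piece in a replicate cannot be told apart from the piece.

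Psmb8 and H2-Q7 were called higher in distal basal cells, and camera called the MHC and interferon list, with 2 of 22 members called, and 4 lists of immune cell markers, none with an estimated correlation (adjusted p from 0.321 to 0.411). If RNA of immune cells on the epithelial plates were the cause, its share would have to reach what Psmb8 and H2-Q7 need. Read from 30 genes typical of each immune type, that share had a median of 0.689% for NK and T cells and 0.730% for Langerhans cells, and the highest single genes gave 1.55% and 2.89%. Psmb8 needed 9.85% and 6.71%, H2-Q7 2.04% and 6.93%; the smallest ratio of needed to highest share was 1.3178, under the factor of 3 set for excluding this cause, so the test cannot tell. The ratio was first 1.0, because H2-Q7 was itself among the typical genes, and both genes were then left out of that set after this was seen.

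The named basal genes differed between ends of unequal sex in replicate 2. If sex were the cause, the fold changes were to fall below 0.5 of their size without the male plates of that replicate. Their median ratio over 27 genes was 0.9808, with a range of 0.8306 to 1.1157. Replicate 3 stays in both fits and all these genes had the same sign there. A fall below 0.5 was thus hardly possible, and the test cannot exclude sex. The ratios do show that the sizes of the fold changes hardly depended on the male plates of replicate 2. In replicate 3 the plates of both ends held mixed sexes.

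Calls were also counted after parting the 6 end sums of an immune class in all 10 ways into 3 and 3. In macrophages 1 of the 10 splits called as many genes as the real one, the real one itself with 1 gene, against at most 0 in the others. In dendritic cells all 10 did, since the real split called 0 genes, and the highest other called 2. Only 4 splits, the real one among them, part the ends of every replicate, and the other 3 of these called 0 genes in both classes. With 10 splits no share under 0.05 can be reached.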

How the results depend on the processing

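Settings with plates or sexes as units, cells of both layers, quality-passed cells, the stomach piece as distal, no male plates and parts of the basal class were chosen after the data were seen; the others were planned. Of 227 counts under alternatives that changed a fit, 96 stayed within 1.5 times the main count and 131 did not. The 96 include permutation tests of shares in epithelium and stroma, and in immune cells with a replicate left out. Those counts were fixed at 0 beforehand, since the smallest p that their orderings allow is 0.0556 or more. Of 818 tested values of named genes, 615 kept direction and call, 203 kept direction only and 0 reversed. A further 114 values, without replicate 2 or 3, have no test and kept their sign. The rule for the largest changes required the same sign in both of these replicates, so for those genes the kept sign was fixed beforehand. Another 14 counts and 75 values come from fits that a setting left as they were and are not counted. Unless said otherwise the cause was not tested. Counts are called genes; proximal against distal counts were 105 in basal cells, 14 in suprabasal cells, 29 in fibroblasts and 4 in the 5 immune classes together.

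With no replicate block the end pieces gave 1, 0, 0 and 0 genes in these classes, the middle piece 0 in every class against either end, and the interaction 0 in place of 51; 60 to 635 genes had an unadjusted p under 0.05 in these fits of edgeR. The block takes up differences between batches, which the fit without it counts as noise. Without the pairing 59 of 60 named genes lost their call, while the counts of called gene lists stayed within 1.5 times.

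DESeq2 called 184 basal, 43 suprabasal, 85 fibroblast and 77 immune genes between the ends. It called 22, 16, 29 and 18 between middle and proximal, in place of 3, 4, 12 and 3, and 76, 12, 15 and 32 between middle and distal, in place of 28, 1, 5 and 10, with 98 for the interaction. With no filter on low counts the end pieces gave 404, 237, 351 and 397, middle against proximal 127, 198, 173 and 267, middle against distal 153, 143, 148 and 247, and the interaction 316. Median-of-ratios scaling gave 11 immune genes between the ends, 7 basal and 13 immune genes between middle and proximal, and 46 basal and 2 suprabasal genes between middle and distal.

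On read counts the end pieces gave 0 basal, 0 suprabasal, 12 fibroblast and 0 immune genes, and the interaction 0. Middle against proximal gave 0 basal, 0 suprabasal, 0 fibroblast and 1 immune genes, middle against distal 0, 0, 0 and 5. In these fits of edgeR 263 to 2232 genes had an unadjusted p under 0.05, and 49 named genes lost their call and none its direction.

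With cells thinned to 5000 UMIs the end pieces gave 135 fibroblast and 20 immune genes; middle against proximal gave 12 basal, 49 fibroblast and 0 immune genes, middle against distal 3 suprabasal, 20 fibroblast and 5 immune genes. Calls of Psmb8, Hoxc6, Edn2 and Clec11a in basal cells were lost, as were those of Id2, Hoxc8, Slc6a2 and Cldn10 in suprabasal cells. Sums of 30 or more cells gave 1 immune gene between the ends, 0 between middle and proximal and 1 between middle and distal, since mast, proliferative immune and T cells could then not be fitted; all sums of the other classes had 30 cells already. In the immune fits of these settings that called 0, edgeR left 78 to 710 genes at an unadjusted p under 0.05.

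Without replicate 1, 2 or 3 in turn, immune genes ranged from 0 to 71 between the ends, from 0 to 39 between middle and proximal and from 1 to 64 between middle and distal, and fits of edgeR that called 0 left 119 to 980 genes at an unadjusted p under 0.05. Mast and proliferative immune cells could be fitted only without replicate 3, so the low ends cover 3 of the 5 classes. Without replicate 1 basal and suprabasal counts between the ends were 101 and 12 and the interaction 40, within 1.5 times; no fibroblast sum of replicate 1 entered the fits. Without replicate 2 or 3 the basal, suprabasal and fibroblast fits have no residual degrees of freedom, so no test was run there. Leaving out the first sequencing run would leave replicate 3 alone and was not run.

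With plates as units the ends gave 37 suprabasal genes, middle against proximal 6 basal, 9 suprabasal, 0 fibroblast (893 at an unadjusted p under 0.05) and 1 immune genes, middle against distal 50, 6, 1 and 2, and the interaction 30. With sexes as units the ends gave 15 fibroblast and 7 immune genes, middle against proximal 7 basal, 6 fibroblast and 1 immune genes, middle against distal 90 basal, 7 suprabasal and 3 immune genes. Few fibroblasts were labelled with a single sex, so this setting and the one without male plates hardly part the sexes in them. Quality-passed cells gave 1 immune gene between middle and proximal and 45 basal genes between middle and distal. Cells of both layers gave 0 immune genes between the ends, 23 between middle and proximal and 0 between middle and distal, and lost Psmb8 and H2-Q7 in basal cells. The stomach piece counted as distal gave 145 fibroblast genes between the ends, 20 fibroblast and 0 immune genes between middle and proximal, 50 basal, 38 fibroblast and 0 immune genes between middle and distal, and 156 for the interaction. In the immune fits of these settings that called 0, edgeR left 110 to 948 genes at an unadjusted p under 0.05.

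Without the male plates of replicate 2 the ends gave 47 basal genes, middle against proximal 1 basal and 2 fibroblast genes, middle against distal 13 basal, 3 fibroblast and 3 immune genes, and the interaction 26. Mast and proliferative immune cells could not be fitted there; the 3 immune genes were all in macrophages, against 1 with all plates. Of 27 named basal genes 13 lost their call, Tnfrsf19, Cyp26b1, Fst and Krt14 among them; fewer cells enter. The proliferative epithelial type alone gave 17 genes between the ends and 13 between middle and distal, and basal cells without it 7 between middle and proximal.

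Of the gene lists, camera called 14 in basal cells, 11 in suprabasal cells, 17 in fibroblasts and 39 in the immune classes. With an estimated correlation it called 0, 0, 0 and 0, fry called 0, 0, 0 and 5, and camera on read counts 8, 4, 9 and 21. Without replicates 1, 2 or 3 in turn the immune lists ranged from 23 to 33, and plates as units gave 20. Of the shares, the permutation, which allows no p under 0.167 in the stroma, called 0 stromal types and edgeR on cell numbers 1.

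With 2 batches at both ends and 1 or 2 residual degrees of freedom, the fits of basal cells, suprabasal cells and fibroblasts rest on spread shared between genes, and small differences go uncalled. Hoxc8 and Mal have 0 to 2 UMIs in one end piece, so depth limits their ratios. Plates lie within pieces, so an effect shared by all plates of a piece in a replicate cannot be told apart from the piece. Spread between plates of a piece enters the fit with plates as units. That fit called 109 basal, 37 suprabasal and 28 fibroblast genes between the ends. The proximal epithelium of replicate 2 had 1 plate only. Nearly all fibroblasts of replicate 2 also came from 1 plate at each end, the plate of mixed sexes. Of 298 distal fibroblasts there, 1 was labelled female and 2 male, and of 369 proximal ones 8 and 4. For fibroblasts, spread between plates was thus hardly measured in replicate 2.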

Other observations

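No hypothesis was tested in this part, and all genes here were chosen after their values were seen.

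Of 7 mitochondrial transfer RNAs of the minus strand tested in basal cells, 5 were called higher in the proximal than in the distal piece: mt-Tn (2.14 ± 0.37, adjusted p = 0.0259), mt-Tq (1.87 ± 0.31, adjusted p = 0.0216), mt-Te (1.56 ± 0.30, adjusted p = 0.0412), mt-Ta (1.47 ± 0.24, adjusted p = 0.0208) and mt-Tc (1.43 ± 0.21, adjusted p = 0.0154), with n = 2 replicates. Not called were mt-Tp (1.27, adjusted p = 0.0868) and mt-Ty, which lay the other way (-0.32). Of 10 on the plus strand 0 were called by edgeR. The medians were 1.47 and 0.46, and 12 messenger RNAs of the plus strand had 0.035 with 0 called, while mt-Nd6 on the minus strand had -0.25. Average mt-Tc was 198 CPM in the proximal, 182 in the middle and 71.8 in the distal piece. In suprabasal cells, fibroblasts and macrophages 0 of 7 transfer RNAs of the minus strand were called. Their medians were 1.15, 0.56 and -0.13, against 0.19, 0.89 and -0.18 on the plus strand. The plus strand thus had the larger median in fibroblasts, but no test compared the strands. Strands are those of the annotation, and the strand that the authors counted is not given in the sources used here.

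Some Hox genes had few UMIs in proximal fibroblasts, though edgeR called none of them. Hoxb5 had 7 UMIs in proximal and 117 in distal fibroblasts of replicates 2 and 3 (-4.36, adjusted p = 0.105), and Hoxc4 20 and 159. In basal cells Hoxc4 had 1008 and 973 UMIs, from unequal totals. That was 85.5 and 125.9 CPM of the pooled totals, and -0.065 by edgeR (adjusted p = 0.942). Hoxb2 was higher proximally in basal cells without a call, with 221 proximal and 42 distal UMIs, or 18.7 and 5.43 CPM (2.15, adjusted p = 0.0830).

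The 35 stomach epithelial cells carried transcripts of several stomach cell types. Of 493360 UMIs, Tff1 made up 26812 CPM, Tff2 17835, Gkn1 17324, Gkn2 12478 and Muc5ac 351, all genes of mucous cells. Pgc, the pepsinogen C gene, had 18031 CPM and the enteroendocrine gene Chga 381.

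The intensity of the CD45 stain separated the sorted cells: medians per group were 10113 to 34373 in immune cells, and -2.38 to 16.45 in other cells apart from the submucosa of replicate 1 with 7119. The Y-linked Ddx3y had 0 UMIs in proximal suprabasal cells of replicate 2 and 12.6 CPM in the distal ones, where both sexes were pooled.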
